A study of Eisenia fetida with 4 samples.

How the data were processed

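The samples are 4 scans of 2 one-colour oligonucleotide arrays. Per the labels, total RNA of adults, juveniles and cocoons of the earthworm Eisenia fetida, pooled into 1 sample, was labelled with Cy3 and hybridised to 2 copies of 1 test array design, 1 of 4 such designs that carry 60-nt probes in sense or antisense orientation. This design is named as an antisense one. The other 3 designs were not analysed here. Labelled cRNA was made from 0.5 ug of RNA with a linear amplification kit, per the labels' protocols. Each array was scanned at a photomultiplier (PMT) gain of 400 and again at 500. The PMT gain sets how strongly the scanner amplifies the light of each pixel.

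The scanner files hold intensities that the authors deposited as GenePix Pro 6.1.0.4 wrote them for a GenePix 4200A scanner at 532 nm and a pixel size of 5, with no normalization, per the file headers. For each spot they give the foreground median and mean, and the median and SD of a local background. They also give, as a percent of the spot's pixels, the saturated pixels, per the file headers. The series' value table equals the foreground median minus the local background median in all 243504 spots of each scan. It is therefore in linear scanner units, unscaled and uncentred, and its columns have medians of 22.0, 86.0, 22.0 and 92.0. No spot carries a quality flag, so leaving out such spots changed nothing.

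Of the 243504 spots, 241399 are test probes, 602 are negative controls and 1503 are positive controls. The test probes are identified by probe number only. Gene names, hits and descriptions are empty for them in the files used here, so no transcript is named, and the counts per target and the keyword gene lists that were planned could not be computed. The rule for naming probes was fixed before the data were examined: up to 2 probes that rose and 2 that fell most with the gain, the 2 brightest at gain 400, the 2 most different between the arrays in each direction, and every kind of control. The alternatives were also listed before the data were examined, except 2 that were added after seeing the data: the position adjustment of the between-array SD, and the replicate block with saturated probes left out.

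A probe was called detected when its foreground median exceeded its local background median by more than 2 SD of the local background, on both arrays at 1 gain. It was called saturated when its foreground median stood at the scanner maximum of 65535. For the effect of the gain, the log2 ratio of background-subtracted foreground medians was taken per array over probes detected and unsaturated in all 4 scans. For the other results, foreground medians were corrected with limma 3.58.1 (R 4.3.3) by normexp with an offset of 50, control spots were left out, and the 4 scans were quantile normalised on the log2 scale. A log2 difference after the offset understates the change of dim probes. Gains were compared per probe with lmFit and eBayes over the 62106 probes detected on both arrays at either gain, with Benjamini-Hochberg adjustment at 0.05.

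There was 1 RNA pool, so the 2 arrays are technical replicates and p-values measure only the spread of hybridisation and scanning. The number of arrays limits the precision of every value. Both scans of an array number are of the same slide, per the labels, so the numbers pair the scans. The deviation of array 2 from array 1 at gain 400 correlated with that at gain 500 over the tested probes (r = 0.68, across probes, which are not independent). The main fit had no block, and a fit with the array number as a block was listed beforehand as the alternative. The limma test was checked on simulated data for the comparison of the gains, with 62106 probes, 200 of them changed. All simulated probes were given the same normal spread, with an SD of 0.178 between arrays and 0.084 between scans, both taken from these data. Without the block it recovered 0 of the 200 changes of 0.5 and 0 of the 200 changes of 1 on the log2 scale. With the block it recovered 199 and 200 of them, with 10 false calls in each run. Real probes need not share 1 spread, so these counts do not give the power of either fit in these data. In these data all gain 400 scans came before the gain 500 scans, per the file headers, so the gain and the scan order cannot be told apart.

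Alternatives were the threshold and reference of detection, the spot summary, the background correction, the normalization, the filter on dim probes, saturated spots, limma with an intensity trend, the value table with values under 1 set to 1, and each array or scan left out. Slide position was examined in 12 bands of rows by 6 bands of columns. Summaries, permutations and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.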

Results

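The data were 4 scans of 2 arrays carrying 241399 test probes for earthworm (Eisenia fetida) transcripts, hybridised with the same pool of RNA from adults, juveniles and cocoons. There were 2 scans at a PMT gain of 400 and 2 at a gain of 500, 1 of each array. The study's stated purpose was to test candidate probes with a single RNA pool. The questions its design poses are which probes gave signal, how well the 2 arrays repeated each other, and what the scanner gain did. The median foreground of the test probes was 64.0 and 63.0 scanner units on arrays 1 and 2 at gain 400, and 202.0 and 208.0 at gain 500.

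Of the test probes, 24.3% gave a signal above their local background on both arrays at gain 400, and 22.9% did so at gain 500. These were 58697 and 55341 probes. Of the 602 negative control spots, which carry a sequence meant not to hybridise, 0 were detected on both arrays at either gain. If the spots were independent, this would allow a share of up to 0.498%. They lie on 1 pair of slides, and the bound is for these control spots only. It does not bound the share of test probes detected in error. On single scans 3 to 8 of the negative control spots passed. A total of 51932 probes were detected at both gains, 6765 at gain 400 alone and 3409 at gain 500 alone. The probes detected at gain 400 alone had a median signal of 61.0 above background on array 1 at that gain, against 223.0 for those detected at both gains. At gain 400, 19624 further probes were detected on 1 array and not the other, and 16808 at gain 500.

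The count depended on the reference used. The median foreground of the test probes lay above that of the negative controls in all 4 scans, at 64.0 against 57.0 on array 1 and 63.0 against 56.0 on array 2 at gain 400. Judged against the 95th percentile of the negative controls, 42.6% of the test probes passed on both arrays at gain 400 and 44.4% at gain 500. Of the 602 negative control spots, 0 passed this reference on both arrays at gain 400 and 2 at gain 500. The reference was set from these same spots, so few could pass. The negative controls thus do not show which of the references is the better one. The order of the gains was thus opposite under the 2 references. No test of these counts was made, since there was 1 RNA pool.

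The signal was concentrated in few probes. At gain 400 the brightest 1% of the probes (2413) held at least 63.4% of the summed background-subtracted signal on array 1 and 63.3% on array 2, and the brightest 10% held at least 88.9% and 88.5%. These are lower bounds, since 165 and 151 probes stood at the scanner maximum. At gain 500, where 940 and 880 did, the brightest 1% held at least 49.0% and 49.1%, so the shares at the 2 gains are not comparable. At gain 400, 144 probes were saturated on both arrays, and 853 were at gain 500. The probes with the highest mean at gain 400 under the naming rule were TA2-133908 and TA2-011613. Both were saturated in all 4 scans at 65535, so their level has only a lower bound and they have no order among the 144. Neither probe is paired with a gene name in the files used here.

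The E1A control probes, which match the adenoviral spike-in transcripts that the array maker supplies, gave signals from the level of the negative controls up to the scanner maximum. Whether spike-in RNA was added is not given in the sources used here, so these values are not read as doses. Each has 60 copies per array. At gain 400, E1A_r60_3 gave 13.5 ± 2.12 (SD, n = 2 arrays) above background, against 12.5 ± 0.707 for the negative controls, and 0 of its copies were detected on both arrays. E1A_r60_a104 gave 17.0 ± 1.41 and E1A_r60_a107 gave 20.5 ± 0.707, also with 0 copies detected. E1A_r60_a135, at 39.3 ± 3.89, was detected in 6 of 60 copies. E1A_r60_a20, at 87.5 ± 0.707, was detected in 50 of 60 copies. All 60 copies of the other 5 were detected: E1A_r60_a22 gave 347.8 ± 16.6, E1A_r60_a97 gave 1073 ± 83.1, E1A_r60_n11 gave 3838 ± 133, E1A_r60_n9 gave 7842 ± 663 and E1A_r60_1 gave 30588 ± 245. At gain 500 all 60 copies of E1A_r60_1 were saturated on both arrays, so its ratio between the gains was not measured.

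**Figure D1:**
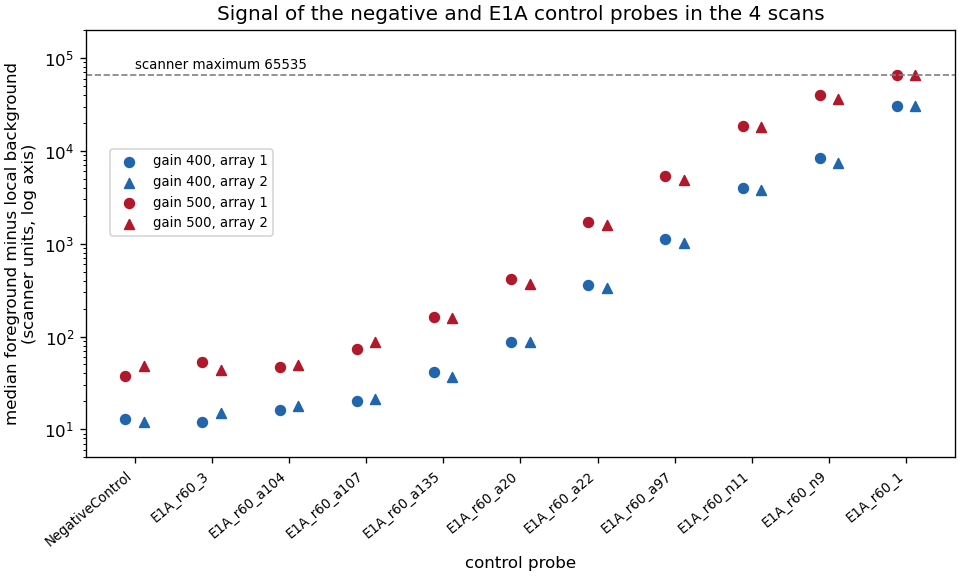
Median foreground minus local background (scanner units, log axis) of the negative control and the 10 E1A control probes, with colour for the gain and symbols for the array. E1A_r60_3 lies beside the negative control at gain 400 (13.5 against 12.5), and E1A_r60_1 reaches the scanner maximum of 65535, drawn as a dashed line, at gain 500.

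Control probes named DCP were present in 3 series. At gain 400 the DCP_1 probes gave 36317 (DCP_1_0), 30019 (DCP_1_1), 20177 (DCP_1_2), 11336 (DCP_1_4), 6557 (DCP_1_7) and 12.5 (DCP_1_11), each as the mean of 2 arrays with 3 spots per array. The last of these equals the mean of the negative controls, and 0 of its spots were detected on both arrays. DCP_22_0 gave 383.0 ± 50.9 and DCP_22_9 gave 16 ± 9.9 (SD, n = 2), the latter with 0 spots detected on both arrays. In the DCP_20 series the 0 and 1 members gave 83.5 ± 6.36 and 85.5 ± 7.78, a difference smaller than the spread between arrays, and DCP_20_9, also with 0 spots detected, gave 13.5 ± 0.707. The 12 probes named RC (120 spots per array) stayed between 8.0 and 15.8 at gain 400, and 0 of these spots was detected on both arrays. The EQC controls gave 15.0 ± 1.41 and the DarkCorner spots 14.5 ± 2.12.

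The arrays repeated each other closely for most probes detected on both of them, on values with the offset added. Over the 58697 probes detected at gain 400, the SD of the log2 difference between array 2 and array 1 was 0.26, and 97.8% of the probes lay within 1.5-fold. Over the 55341 probes detected at gain 500 the SD was 0.27, and 97.2% lay within 1.5-fold. Pearson's r over probes was 0.987 at gain 400 and 0.986 at gain 500, and Spearman's rho was 0.971 and 0.969. These correlations are across probes of 1 RNA pool, and probes are not independent replicates. Probes that passed on 1 array only, 19624 at gain 400 and 16808 at gain 500, were left out. The 1.5-fold shares are of values with the offset added, which understates the differences of dim probes. With no filter on dim probes the SD was 0.36 at gain 400 and 0.37 at gain 500. From the value table it was 0.33 and 0.34, and with pixel means 0.23 and 0.24. Each side was 1 hybridisation, so no test of a difference between the arrays was possible.

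A total of 308 probes (0.525%) differed by more than 2-fold between the arrays at gain 400, of which 304 were higher on array 2 and 4 were lower. All 308 had the same direction at gain 500, and 261 were again more than 2-fold apart. The largest excesses on array 2 were those of TA2-207500 and TA2-232897. TA2-207500 had foregrounds of 236 on array 1 and 4486 on array 2 at gain 400, a normalised log2 difference of 4.39 (3.86 at gain 500). TA2-232897 had foregrounds of 536 and 9248, a log2 difference of 4.24 (4.65 at gain 500). They lie close together on the slide, at row 786, column 242 and at row 790, column 240. The largest deficits on array 2 were those of TA2-128500, with foregrounds of 1328 and 148 and a log2 difference of -3.17 (-3.86 at gain 500), and TA2-080215, with 216 and 76 and a difference of -1.65 (-1.44 at gain 500).

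The difference between the arrays depended on the place of a probe on the slide. Before normalization, the median log2 difference of array 2 against array 1 at gain 400 was -0.23 in rows 381 to 456, in the middle of the slide. It was 0.08 in rows 685 to 760 and -0.06 in the last 76 rows. At gain 500 the same bands gave -0.22, 0.14 and -0.02. Removing the median of each of the 72 slide cells lowered the SD between the arrays from 0.26 to 0.23 at gain 400 and from 0.27 to 0.24 at gain 500, a setting chosen after seeing the data. The share of probes detected at gain 400 was 22.5% and 22.3% in the first and last bands of rows and 25.9% in band 7. Copies of the 5 brightest E1A controls varied more within array 1 than within array 2: for E1A_r60_n9 the coefficient of variation over 60 copies was 22.6% against 13.5%, and for E1A_r60_a97 21.0% against 11.6%. Other controls went either way, with 20.9% against 15.6% for ETG05_36762, 19.1% against 19.9% for E1A_r60_a20 and 9.58% against 13.1% for GE_BrightCorner.

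**Figure D2:**
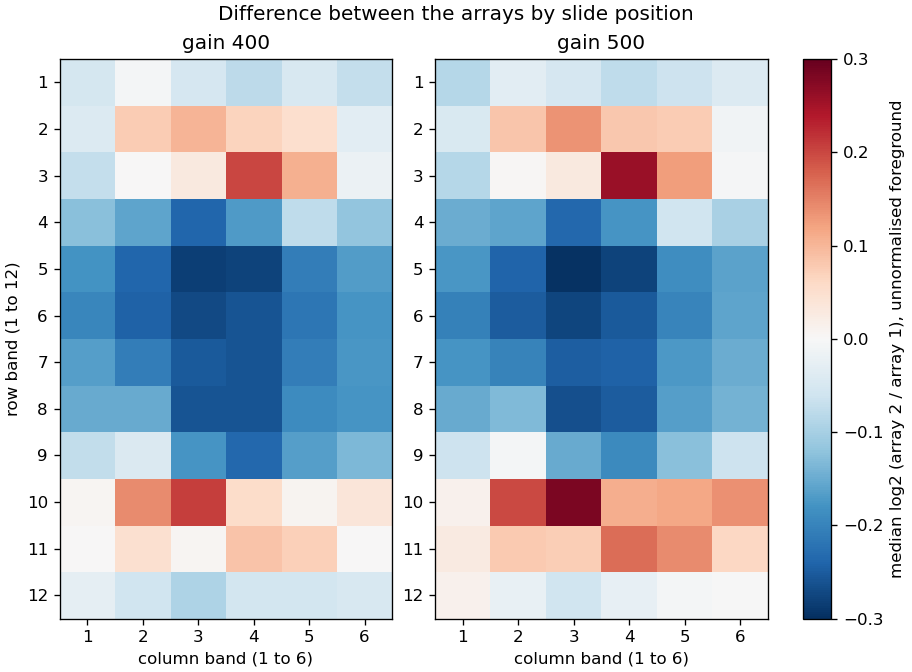
Median log2 ratio of array 2 over array 1 (unnormalised foreground, colour) of detected test probes in 12 bands of rows (vertical axis) and 6 bands of columns (horizontal axis), for both gains. Cell medians run from -0.28 to 0.21 at gain 400 and from -0.30 to 0.28 at gain 500, with the lowest values in the middle rows in both panels.

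Raising the gain from 400 to 500 multiplied the signal by 4.70 on array 1 and 4.78 on array 2, a log2 ratio of 2.25 ± 0.017 (SD, n = 2), over 50966 probes detected and unsaturated in all 4 scans. Among controls the ratio was 4.76 ± 0.017 for E1A_r60_a97, 4.78 ± 0.034 for E1A_r60_n11 and 4.87 ± 0.048 for E1A_r60_n9. The median of the local background rose 2.95-fold on both arrays, and its SD rose 4.88-fold on array 1 and 5.09-fold on array 2. Among probes detected on both arrays at both gains, the gain ratio changed little with the level of the probe up to saturation. It went from a log2 of 2.22 ± 0.026 for probes at 50 to 100 units to 2.27 ± 0.011 for those at 3000 to 10000. Above 10000 units at gain 400, 853 of 1177 test probes were saturated at gain 500 on both arrays, so the median of 1.56 in this bin is set by the scanner maximum. The lowest bin, under 50 units, held 140 probes and gave 2.39 ± 0.027. A dim probe enters these bins only if it was also detected at gain 500, which can favour dim probes with a high ratio. Over all unsaturated probes, detected or not, the log2 ratio was 2.17.

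**Figure D3:**
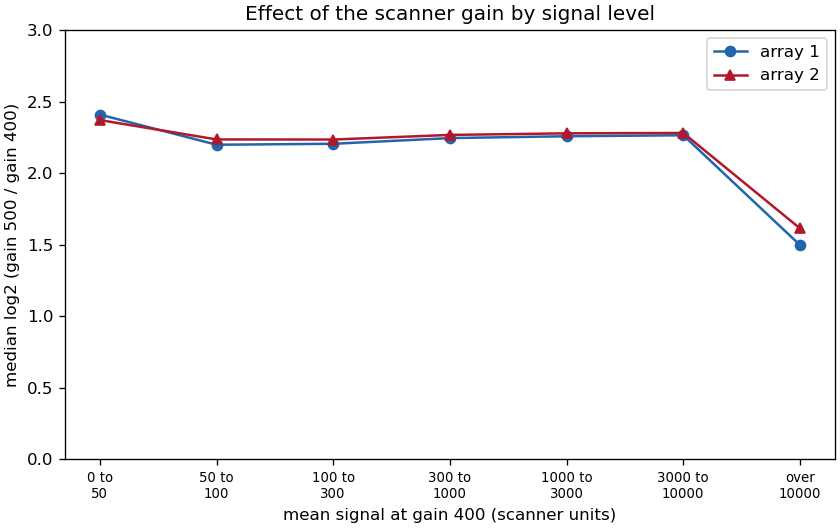
Median log2 ratio of gain 500 over gain 400 (vertical axis) for each array, by the mean background-subtracted signal at gain 400 in scanner units (horizontal axis). Only probes detected on both arrays at both gains are included. The mean over both arrays lies between 2.22 and 2.39 up to 10000 units. The last point, 1.56, is set by the scanner maximum, where 853 of 1177 probes stood at gain 500, and does not measure the gain.

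After quantile normalization, 0 of the 62106 tested probes differed between the gains (limma, Benjamini-Hochberg adjusted p under 0.05, smallest adjusted p 0.178), and 1153 had an unadjusted p under 0.05. That count cannot be set against chance, since the fit without the block leaves the difference between the arrays in its error. With the array as a block, which the shared slides call for, the count was again 0, with a smallest adjusted p of 0.126. In that fit 4070 had an unadjusted p under 0.05, where chance gives about 3105 if probes are independent, which they are not. Without the gain 500 scan of array 2 the count was 1. In simulated data with 200 of 62106 probes changed, the fit without the block recovered 0 of 200 changes of 1 on the log2 scale. It thus had little power there for changes in few probes. With the block 200 of 200 were recovered. All simulated probes had the same spread, so the power of either fit in these data is not known. The SD of the log2 change over all tested probes was 0.13. For 48 probes the change was over 1 in size, but none of these passed with or without the block. Since no probe passed the test, none is named as changed by the gain. Quantile normalization gives all scans 1 distribution, so this comparison is of each probe relative to the others. It also removes changes that follow the signal level. The log2 ratio of 1.56 above 10000 units, set by the scanner maximum, is such a change. The count of 0 therefore does not show that relative levels were unchanged across signal levels. With no normalization, 61756 probes were higher and 0 lower at gain 500, and with median scaling 53826 were higher and 401 lower.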

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

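The results below were noted because control probes that the comparisons do not use gave signal above the negative controls. ETG05_36762, with 40 spots per array, gave a mean signal of 118.8 at gain 400, against 12.5 for the negative controls, and 38 of its 40 spots were detected on both arrays. The 12 other ETG controls gave 9.5 to 16.5, with 0 of 480 spots detected. GE_BrightCorner, with 14 spots per array, gave a mean signal of 240.0 at gain 400. For both, array 2 gave more signal than array 1: 1.40-fold for ETG05_36762 and 1.5-fold for GE_BrightCorner at gain 400, and 1.42-fold and 1.46-fold at gain 500. Over the same arrays the 6 brightest E1A controls gave between 0.887 (E1A_r60_n9) and 0.989 (E1A_r60_1) times as much on array 2 at gain 400. Each side was 1 hybridisation, so this was not tested.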

How the results depend on the processing

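Of 52 alternatives computed, 29 stayed within the range set for their result (1.5 times for a count, the spread between arrays for the gain ratio, the 95% interval of the SD for the between-array SD) and 23 moved. The interval of the SD takes probes as independent, which they are not, so it is too narrow (0.2570 to 0.2599 at gain 400). Every alternative of the between-array SD left it, which does not by itself show that the processing matters. Some of the 29 could not move. With 2 arrays, the gain ratio of 1 array always lies within their spread. Keeping flagged spots changed nothing, as no spot is flagged. The detected count at gain 400 moved to 88268 with 1 SD of the local background and to 102760 against the negative controls, and at gain 500 to 107143 against the negative controls. It stayed within 1.5 times with 3 SD (47129 and 44798) or pixel means. With 1 array alone it ranged from 68168 to 68850 at gain 400 and from 62876 to 64614 at gain 500. The saturated count ranged from 151 to 165 and from 880 to 940 with 1 array alone. The gain ratio was 2.15 with no background correction and 2.17 over all unsaturated probes, and 2.23 and 2.26 on single arrays. The between-array SD at gain 400 and at gain 500 was 0.23 and 0.29 with median scaling or no normalization, which are equal by construction, 0.25 and 0.26 with no background correction, 0.36 and 0.37 with no filter on dim probes, 0.23 and 0.24 with pixel means, 0.33 and 0.34 from the value table, and 0.23 and 0.24 after the position adjustment, which was added after seeing the data. The count of probes that differ between the gains was 0 with the replicate block, 0 with the block and saturated probes left out, which was also added after seeing the data, and 0 to 1 with 1 scan left out, where a lone scan is assumed to vary like the others; the 1 came without gain 500 array 2. It was 2 from the value table, 54227 with median scaling and 61756 with no normalization. In the last 2 the median log2 change of the tested probes was 0.73 and 1.94, which these settings leave in the values, whereas it was -0.0012 in the main fit. Counts of targets and shares of gene lists were not run, since the files used here name no targets. Dim probes are limited by signal over background: E1A_r60_a135, at 39.3 units at gain 400, was detected in 6 of its 60 copies.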

Other observations

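The tests of the gain 400 against gain 500 maps, of the probe numbers, of the direction of the differences between the arrays, of local blemishes (2 of the probes had been seen to lie close together) and of the isolated probes were chosen after the result was seen, at least in part, as were the 5 E1A controls used, and the values on the lower array were added afterwards to the test of dim spots. No biological explanation was tested for these patterns, since 1 RNA pool was used throughout, except where said.

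The share of detected probes changed along the probe numbers. Over consecutive blocks of 10000 numbers, 18.6% (numbers 60001 to 70000) to 30.6% (230001 to 240000) of the probes were detected on both arrays at gain 400, a range of 12 percentage points, where the highest of 1000 shuffles of the numbers gave 4.58. This argues against a chance order. Slide position does not account for it either: with the 72 slide cells weighted equally the range was 11.96 percentage points, and the probe number was almost unrelated to the row (Spearman's rho 0.0023) and column (-0.0015). Neighbouring numbers had a rank correlation of signal of 0.037 at a distance of 1 (highest shuffle 0.0066) and 0.019 at 10, which is small but above chance at a distance of 1. A candidate explanation is that the numbers follow the order in which sets of target sequences of different expression entered the design; this stays open, as the files used here do not pair numbers with targets.

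The lower signal of array 2 in the middle rows followed the place on the slide. Copies of the 5 brightest E1A controls at different places differed between the arrays along with the test probes around them (Pearson's r 0.781, Spearman's rho 0.885, 300 copies, permutation p 0.0001, the smallest that 10000 permutations within controls can give). The permutations take copies as exchangeable, although copies in the same slide cell share 1 median and all come from 1 pair of slides. The p-value thus overstates the evidence. For E1A_r60_n11 the median was -0.20 in row bands 5 to 8 and 0.09 elsewhere, relative to its own median. A fault of a single scan is argued against by the correlation of 0.983 between the 72 cell medians at the gains, which came from separate scans. An uneven hybridisation or wash of 1 or both slides may give this and stays open.

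The 308 probes more than 2-fold apart between the arrays were partly grouped on the slide. Of them, 55.8% had another within 5 rows and 5 columns. In 1000 random draws of detected probes this share had a median of 13.6% and a highest value of 24.0%. The draws took no account of the slide-wide trend. In 1 of the 72 cells lay 57 of the 308 probes, all 57 higher on array 2. Local blemishes may thus account for part of the 172 grouped probes, all of them higher on array 2, as some would lie near another by chance. Noise of dim spots stays open. The median signal of the 308 probes, 309.8, was above the 182.5 of all detected probes, the bound set beforehand. That bound was wrong: the signal includes the array on which they are high, and the offset of 50 keeps dim probes from passing 2-fold. On the lower of the 2 arrays their median was 153.0, between the 25th percentile of 86.0 and the median of 167.0 of detected probes. Noise that goes either way cannot account for all 308, since 98.7% were higher on array 2 (603 against 166 over probes detected on at least 1 array), but noise skewed to 1 side on a slide stays open, as both gains read the same hybridised spots. The other 136 stood alone, and 132 of these were also higher on array 2; 1.47% of them had another within 5 probe numbers (highest draw 5.88%), which leaves a shared sequence open.

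The DCP_1_0, DCP_1_1 and DCP_1_2 controls gave 0.764, 0.793 and 0.777 times as much signal on array 2 as on array 1 at gain 400, whereas DCP_1_4 and DCP_1_7 gave 1.00 and 1.03 times as much. Each has 3 spots per array, and these ratios are not adjusted for slide position. At gain 500 all 3 spots of DCP_1_0, DCP_1_1 and DCP_1_2 were saturated on both arrays, so their ratios have no second reading. E1A_r60_1, with 60 copies and a signal of 30588 at gain 400, gave 0.989 times as much. In the dimmer DCP_22 series no spot was saturated on both arrays. At gain 400 DCP_22_0, DCP_22_2, DCP_22_4 and DCP_22_6 gave 0.828, 0.821, 0.914 and 1.16 times as much on array 2. At gain 500 the same controls gave 0.835, 0.827, 0.974 and 1.15 times as much. A lower signal on array 2 was thus not confined to the brightest DCP controls.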
